A study of Mus musculus with 7 samples.

How the data were processed

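RNA was measured in 7 sequencing libraries from the midbrain of untreated adult mice of the line Stard8-TRAP ES2342. In this line a ribosomal protein, Rpl10a, fused to the green fluorescent protein EGFP, is expressed under regulatory sequence of Stard8. Translating ribosome affinity purification (TRAP) pulls the tagged ribosomes, with the RNA they carry, out of a tissue homogenate on beads coated with antibodies against EGFP. The libraries were of 2 kinds, the immunopurified RNA (IP, 3 libraries, replicates 1, 2 and 4) and the RNA that did not bind to the beads (unbound, 4 libraries, replicates 1 to 4). An IP library numbered 3 was not analysed here.

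The deposited values were whole-number read counts per gene symbol, without normalization. Reads were aligned to the mouse genome build mm10 with STAR 2.0.0e and counted with HTSeq, per the submitters' processing notes. The gene annotation, the strand setting and the read filters are not given in the sources used here. Reads from overlapping genes, antisense partners and near-identical copies, such as the beta-globin or histone genes, may therefore be missing from the gene rows or fall on another row. Each file listed 32531 gene symbols and 6 rows that name no gene. These rows were left out of library sizes and tests. Reads outside any gene made up 16.6% ± 2.78 of all reads in the files for IP and 12.2% ± 0.708 for unbound (SD, n = 3 and 4). Reads that matched more than 1 gene, and were assigned to none, made up 1.55% ± 0.107 and 9.95% ± 1.89. Reads aligned to more than 1 place made up 36.5% ± 3.28 and 24.5% ± 7.28. Both kinds were left out of the gene counts, which may shift the fold changes of overlapping or duplicated genes. No row carried the symbol of a mitochondrially encoded gene, so that list, fixed before the data were examined, held 0 measured genes.

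The libraries held between 52052340 and 76114634 counts in genes, and the lowest level that 3 counts represent was between 0.0376 and 0.059 CPM (counts scaled to the effective library size, the count in genes times the TMM factor). Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. No pair of libraries of the same group agreed within sampling noise. The chi-square statistic per degree of freedom over genes lay between 82.6 and 1264.

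Counts were analysed in R 4.3.3 with edgeR 4.0.16: low counts were removed with filterByExpr, which left 17654 genes, libraries were scaled by TMM, and IP was tested against unbound with the robust quasi-likelihood test (2-sided), adjusted by Benjamini-Hochberg at 0.05. CPM and log2 fold changes were computed here from the deposited counts, and errors of log2 fold changes are standard errors. Of the tested genes, 15612 (88.4%) had the same symbol in GENCODE M21, whose build, GRCm38, is the one named mm10. Coordinates were taken from it. Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with an inter-gene correlation preset to 0.01, adjusted over the 34 lists with at least 2 measured members. The alternatives were camera with an estimated correlation and fry. Shares of counts were compared with an exact permutation test over all 35 splits of the libraries into 3 and 4, for which the smallest possible p is 0.0286, and adjusted over 19 measures.

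The design, the 35 gene lists, the rule for named genes and the alternatives were fixed before the data were examined. Named were Stard8 and Rpl10a, then the 12 highest and 12 lowest log2 fold changes among genes past the threshold, with a mean CPM of at least 5 and no overlap between the groups. Symbols of the form Gm with digits or ending in Rik were passed over (2 among the highest and 2 among the lowest). Every member of the transmitter identity list was named. Of each other list the rule took the member with the smallest p, the most abundant member, and the leading member past the threshold against the majority. Some genes that the rule takes are not reported here. Genes named outside this rule are said to be chosen after their values were seen. A further 13 lists were written after the data were examined and are used in the closing section alone.

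The alternatives were RLE scaling, library size only, no low-count filter, a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma voom, the replicate number as a block, the index sequence as a covariate, fits within each index sequence, leaving out the 10 most abundant genes, glmTreat with a log2 threshold of 0.5, and leaving out each library. Leaving out both IP 4 and unbound 2 was added after seeing the data. On simulated counts of IP against unbound over 17654 genes, with 200 genes changed, the test called 51% of the 4-fold and 7% of the 2-fold changes. Of its calls, 6.45% were unchanged genes (4 genes). A simulated list raised 4-fold was called, and 0 of 30 unchanged lists. Genes were simulated independently of each other, so the simulation does not show how often lists of correlated genes are called wrongly. Far fewer genes were changed than the 39.4% that passed in the data, so its rates may not carry over.

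The labels give a sequencing lane and 1 of 2 index sequences for each library. IP libraries were read in lanes 2 and 5 and unbound libraries in lanes 1 and 3, so lane and group cannot be told apart. The labels do not say whether the 2 kinds of library were prepared alike, and a difference in preparation could not be told apart from the group either. Each index sequence was used in both groups. The labels do not say that replicates came from separate animals, so p-values measure the spread between these libraries, which may be technical.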

Results

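The data were read counts from 3 libraries of ribosome-bound RNA (IP) and 4 libraries of unbound RNA from mouse midbrain. The submitters describe the series as profiling neurons of the Stard8-TRAP line. The single comparison asks which transcripts were enriched on the tagged ribosomes over the RNA left behind. Counts in genes were 70861941, 52501956 and 52052340 in IP 1, 2 and 4, and 76114634, 67928765, 53715780 and 56543182 in unbound 1 to 4. Correlations of log2 CPM over genes were 0.948 to 0.972 among IP libraries, 0.914 to 0.978 among unbound libraries and 0.769 to 0.846 between the groups. Genes are not independent replicates in these correlations.

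Lists of blood vessel and macrophage genes had the highest median fold changes in IP, and all pan-neuronal and most oligodendrocyte genes were lower. Stard8, the gene whose regulatory sequence drives the tag, encodes a protein with a lipid-transfer domain. It measured 352 ± 111 CPM in IP (SD, n = 3) and 4.23 ± 0.569 CPM in unbound (SD, n = 4). Its log2 fold change was 6.38 ± 0.31 (adjusted p = 6.67e-07), from 29121, 25261 and 11570 counts in IP 1, 2 and 4. Stard8 lies on chromosome X from 99003248 to 99074728 (GRCm38, plus strand, protein coding). Rpl10a, whose coding sequence the transgene carries (chromosome 17, 28328471 to 28331033), had 328 ± 40.4 CPM in IP and 164 ± 119 in unbound, a log2 fold change of 1.0 ± 0.51 that did not pass the threshold (adjusted p = 0.142). Without unbound 2 it was 1.57 (adjusted p = 0.0129).

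Of 17654 genes tested, 6950 (39.4%) passed the threshold, 3622 higher and 3328 lower in IP. An absolute log2 fold change of at least 1 was met by 3062 and 2761 of these. Groups did not overlap in 47.7% of genes, against 5.71% by chance, with 4429 genes above and 3999 below every unbound library. Within index ACAGTG (2 IP, 2 unbound) 3840 genes passed, 2190 higher and 1650 lower. Within index GTGAAA (1 IP, 2 unbound, the lone IP library assumed to vary like the unbound ones) 7259 passed. The number of lower genes was 1899 without IP 1 and 1751 without IP 2, and the total without IP 2 was 4547. IP 4 stood closer to unbound RNA than the other IP libraries. Pan-neuronal genes took 1.26% of its counts, against 0.647% in IP 1 and 0.696% in IP 2.

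Of the 12 highest genes, Foxf2 and Higd1b were in the pericyte and smooth muscle list, Lyve1 was in the microglia and macrophage list, and 9 were in none of the lists. AW549542 had 16.6 ± 4.73 CPM in IP and 0 counts in every unbound library, at least 1410-fold higher against a floor of 3 counts over the unbound group. Ripply3, a transcriptional corepressor (chromosome 16, 94328420 to 94336935), had 2 unbound counts in all, a ratio of 1640 with a 95% exact counting interval of 454 to 13600. Foxf1 and Foxf2, forkhead transcription factors, rose by 9.01 ± 0.69 and 8.68 ± 0.73 on the log2 scale. Gper1, a membrane estrogen receptor, rose by 9.05 ± 0.77, from 0.31 ± 0.217 to 159 ± 32.2 CPM. The macrophage genes Ms4a7 (8.78 ± 0.76) and Lyve1 (8.50 ± 0.49), the latter a hyaluronan receptor, and the pericyte gene Higd1b (8.48 ± 0.90) followed. The remaining 4 were BC057675 (9.85 ± 0.90), the metalloreductase Steap4 (9.34 ± 0.73), the leukotriene receptor Cysltr2 (9.27 ± 0.90) and the siderophore-binding protein Lcn2 (8.33 ± 0.85). Adjusted p for these 12 genes lay between 1.36e-06 and 4.54e-05.

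Among the 12 lowest genes, 9 carried accession-like or provisional symbols without an entry in GENCODE M21. AK140265 alone had 46000 ± 6293 CPM in unbound and 1176 ± 1506 in IP (log2 fold change -5.29 ± 0.90, adjusted p = 0.00108), with 148179 counts in IP 4 against 17131 in IP 1 and 22205 in IP 2. The others were GU332589 (-5.41 ± 0.84), AK163440 (-4.51 ± 0.59), X57780 (-4.24 ± 0.70), AI450353 (-4.14 ± 0.88), DQ539915 (-4.11 ± 0.66), AK018753 (-4.06 ± 0.74), AK085136 (-3.69 ± 0.59) and AK142750 (-3.65 ± 0.73). The relaxin family peptide Rln3 (-3.57 ± 0.70), hypocretin, Hcrt (-3.40 ± 0.69), and the beta-globin gene Hbb-bs (-3.38 ± 0.76) completed the set.

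All 26 endothelial genes and all 19 pericyte and smooth muscle genes rose in IP, over all genes and adjusted over the list alone. Their median log2 fold changes were 6.64 and 5.82 (camera adjusted p = 6.43e-18 and 7.21e-13). With the correlation estimated from the data these calls were lost, with adjusted p = 0.0986 with an estimated correlation for the first and adjusted p = 0.162 with an estimated correlation for the second. Ly6a, a surface antigen of endothelial cells, rose from 2.53 ± 0.49 to 626 ± 71.3 CPM, and Slc2a1, the glucose transporter of the blood-brain barrier, from 42.8 ± 9.26 to 982 ± 249 CPM. Rgs5, a pericyte regulator of G protein signalling, rose from 9.07 ± 1.67 to 2309 ± 603 CPM and Myl9, a myosin light chain, by 7.63 ± 0.30 on the log2 scale. Together the lists took 1.15% ± 0.245 of counts in IP and 0.0171% ± 0.00285 in unbound (exact permutation p = 0.0286, adjusted p = 0.0494). The share of each list is also among the 19 measures, so this adjusted p, close to 0.05, rests on overlapping measures. The joint share was 0.87% in IP 4 against 1.27% and 1.31% in IP 1 and 2. Within index ACAGTG 26 endothelial and 17 mural genes passed, and within index GTGAAA 26 and 18.

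All 23 microglia and macrophage genes rose too, by a median of 4.16 (camera adjusted p = 1.07e-15, and adjusted p = 0.138 with an estimated correlation), with the same count adjusted over the list alone. C1qc, a complement component, rose from 9.41 ± 5.02 to 276 ± 34.9 CPM and the coagulation factor subunit F13a1 from 1.71 ± 0.768 to 183 ± 7.97. Astrocyte genes rose less, 13 of 20 (15 adjusted over the list alone) by a median of 1.05 (camera adjusted p = 0.000128, and adjusted p = 0.23 with an estimated correlation). The intermediate filament gene Gfap rose from 65 ± 5.99 to 286 ± 17.9 CPM, while glutamine synthetase, Glul, the most abundant, had a log2 fold change of 0.61 ± 0.25 (adjusted p = 0.0728, and 0.0412 without unbound 1). Fibroblast and meningeal genes rose in 8 of 16 (10 adjusted over the list alone), median 1.69 (camera adjusted p = 0.00377, and adjusted p = 0.277 with an estimated correlation). Fibronectin, Fn1, rose by 4.98 ± 0.47, and Ptgds, the prostaglandin D2 synthase, had -0.27 ± 0.55 (adjusted p = 0.734, and -1.30 with adjusted p = 0.0499 without IP 4). Of 14 ependymal and choroid plexus genes, 5 rose, Rarres2 by 4.14 ± 0.47 (2 rose without IP 1, and 3 without unbound 1 or unbound 4), and Enpp2 fell by 1.17 (adjusted p = 0.0431), with 6 and 1 adjusted over the list alone. That list was not called (adjusted p = 0.0643), but it was without IP 1 (adjusted p = 0.0471) or IP 2 (adjusted p = 0.0318), where Enpp2 lost its call (adjusted p = 0.157 and 0.164), as it did without unbound 3 or unbound 4 (adjusted p = 0.1 and 0.0974). Erythroid genes fell in 5 of 6, also adjusted over the list alone (camera adjusted p = 0.00575, and adjusted p = 0.261 with an estimated correlation). Hbb-b2 had the smallest p (-2.78 ± 0.59), Hbb-bs fell furthest (-3.38 ± 0.76), and Bpgm had -0.16 ± 0.23.

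**Figure D1:**
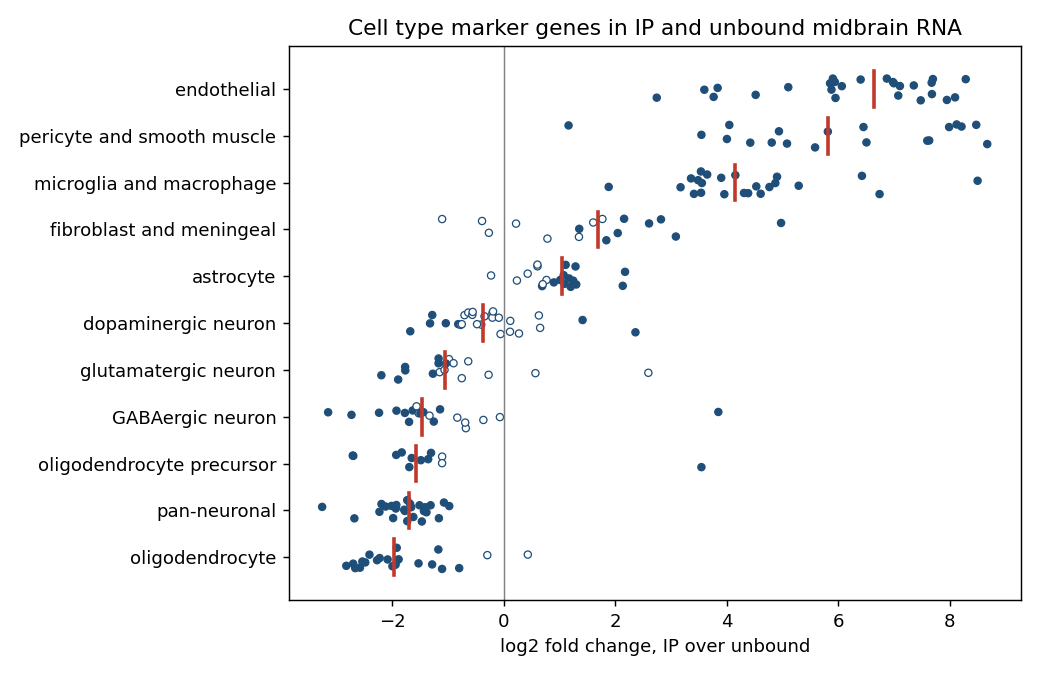
Log2 fold change of IP over unbound for each measured gene of 11 lists of cell type markers, from edgeR over 3 IP and 4 unbound libraries. Filled points passed an adjusted p of 0.05, open points did not, and red bars are list medians, which run from 6.64 for endothelial genes to -1.97 for oligodendrocyte genes.

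Pan-neuronal and axonal genes were lower in IP. All 26 pan-neuronal genes fell, also adjusted over the list alone, by a median of -1.70 (camera adjusted p = 1.29e-08, and adjusted p = 0.261 with an estimated correlation). Without IP 1 the count was 17 and without IP 2 it was 16. Snap25, a synaptic vesicle fusion protein, fell from 12127 ± 2613 to 3522 ± 1682 CPM, and the noncoding Snhg11 by 3.26 on the log2 scale. Axon initial segment and cytoskeleton genes fell in 16 of 20 (17 adjusted over the list alone, camera adjusted p = 1.13e-05, and adjusted p = 0.263 with an estimated correlation), including the spectrin Sptbn4 (-2.48 ± 0.29) and Map1b (-1.62 ± 0.51). Without IP 2 this count was 9, without IP 1 it was 10, and Map1b lost its call without either (adjusted p = 0.118 and 0.103) and without unbound 3 or unbound 4 (adjusted p = 0.0555 and 0.068). Oligodendrocyte genes fell in 20 of 22, also adjusted over the list alone, by a median of -1.97 (camera adjusted p = 1.54e-07, and adjusted p = 0.261 with an estimated correlation). The myelin gene Mbp fell by 2.70 on the log2 scale. Oligodendrocyte precursor genes fell in 9 of 12 and 1 rose (11 and 1 adjusted over the list alone, camera adjusted p = 0.00186, and adjusted p = 0.184 with an estimated correlation). Bcas1 fell by 1.83, and Cspg4, the NG2 proteoglycan, which pericytes also carry, rose by 3.55 ± 0.23.

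Transmitter identity genes gave 8 lower and 0 higher of 20 (8 and 1 adjusted over the list alone, camera adjusted p = 0.00377, and adjusted p = 0.345 with an estimated correlation). The glutamate transporter Slc17a6 fell by 1.76, the GABA synthesis genes Gad1 and Gad2 by 1.44 and 1.77, and the GABA transporter Slc32a1 by 1.92. Also lower were the dopamine transporter Slc6a3 (-0.82 ± 0.25, adjusted p = 0.0234), the serotonin transporter Slc6a4 (-1.33 ± 0.48), the choline transporter Slc5a7 (-2.39 ± 0.68) and the nitric oxide synthase Nos1 (-1.08 ± 0.37). The count was 5 without unbound 3 and 3 without IP 1. Without IP 2 the count was 3, and Slc6a3, Slc6a4, Slc5a7, Nos1 and Gad1 had adjusted p = 0.116, 0.147, 0.0777, 0.154 and 0.0588, and without IP 1 adjusted p = 0.111, 0.161, 0.07, 0.136 and 0.0503. Slc6a3, Slc6a4 and Nos1 also lost their calls without unbound 3 (adjusted p = 0.0668, 0.108 and 0.0717). Slc6a4 lost its call without unbound 2 or unbound 4 (adjusted p = 0.0576 and 0.111) and Nos1 without unbound 1 or unbound 4 (adjusted p = 0.0714 and 0.101). Without IP 4 the count was 15. Tyrosine hydroxylase, Th, which makes the dopamine precursor, had 64.5 ± 3.75 CPM in IP and 59.4 ± 13.4 in unbound (log2 fold change 0.12 ± 0.23, adjusted p = 0.714). Ddc, which makes dopamine, had 0.63 ± 0.23 (adjusted p = 0.0516), and without IP 4 it was 0.84 (adjusted p = 0.0144). The vesicular transporter Slc18a2 had -0.77 ± 0.32 (adjusted p = 0.0767, and adjusted p = 0.0465 and 0.043 without unbound 1 and unbound 2). Tph2, Chat, Slc18a3, Slc6a5, Dbh, Slc6a2, Slc17a7, Slc17a8 and Hdc did not pass, with log2 fold changes between -3.06 for Slc6a2 and 0.00 for Hdc. Without IP 4 all of these but Slc6a2 and Hdc passed as lower, with Slc17a7 at -2.05 (adjusted p = 0.00826), and Tph2 and Chat passed without unbound 1 as well (adjusted p = 0.023 and 0.0422).

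**Figure D2:**
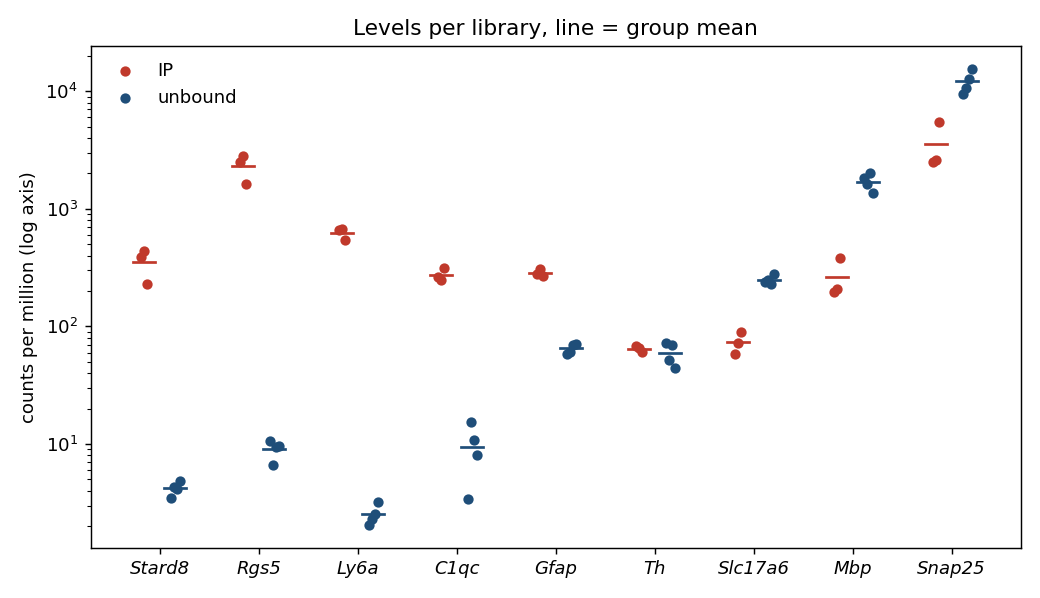
Levels in CPM on a log axis for 9 genes in each of 3 IP (red) and 4 unbound (blue) libraries, with lines at the group means. Stard8, Rgs5, Ly6a, C1qc and Gfap lay higher in every IP library, Slc17a6, Mbp and Snap25 lower, and Th overlapped.

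The dopaminergic neuron list was not called (5 of 26 lower and 2 higher, also adjusted over the list alone, median -0.37, camera adjusted p = 0.182), though the list test fry called it as lower (adjusted p = 0.0273). Its higher members were Gch1, which makes the cofactor of tyrosine hydroxylase (2.36 ± 0.32), and the aldehyde dehydrogenase Aldh1a1 (1.42 ± 0.33). Its lower count was 8 without unbound 2, 2 without IP 2, and 3 without IP 1 or unbound 3. GABAergic genes fell in 11 of 20 and 1 rose, also adjusted over the list alone (camera adjusted p = 0.000258, and adjusted p = 0.261 with an estimated correlation). The riser was the transcription factor Gata2 (3.85 ± 0.25), which endothelial and blood cells also express. Glutamatergic genes fell in 8 of 17 (10 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.00185, and adjusted p = 0.261 with an estimated correlation), including Tcf7l2 (-1.17 ± 0.29), which lost its call without IP 2 (adjusted p = 0.0536). Cholinergic and motor genes fell in 7 of 14 (9 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.000952, and adjusted p = 0.23 with an estimated correlation), with Prph at -2.97 ± 0.40 and Ache at -2.22 ± 0.33. Without IP 2 these glutamatergic and cholinergic counts were 5 and 4. Serotonergic genes gave 3 higher and 4 lower of 16 (4 and 5 adjusted over the list alone) and were not called (adjusted p = 0.287), with 7 lower without IP 4. Noradrenergic genes gave 1 higher, the monoamine oxidase Maoa (1.79 ± 0.21), and 2 lower of 10, also adjusted over the list alone (adjusted p = 0.581).

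Neuropeptide genes fell in 15 of 32 and 2 rose (18 and 2 adjusted over the list alone, camera adjusted p = 0.000164, and adjusted p = 0.261 with an estimated correlation). Endothelin 3, Edn3, rose by 4.32 ± 0.33, and cholecystokinin, Cck, the most abundant, had -0.80 ± 0.40 (adjusted p = 0.136, and -1.26 with adjusted p = 0.0381 without IP 4). Midbrain patterning factors gave 19 lower and 7 higher of 53 (24 and 7 adjusted over the list alone, camera adjusted p = 0.00772, and adjusted p = 0.162 with an estimated correlation). Receptors coupled to G proteins gave 24 lower and 3 higher of 55 (27 and 4 adjusted over the list alone, camera adjusted p = 1.02e-05, and adjusted p = 0.261 with an estimated correlation). Gabbr1 fell by 1.03, and Adora2a, an adenosine receptor, rose by 6.90 ± 0.51. Without IP 1 or IP 2 the lower counts were 11 and 11 for the patterning factors and 14 and 14 for the receptors, and Gabbr1 had adjusted p = 0.0522 and 0.0656.

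Ion channel and receptor subunit lists moved the same way. Potassium channels gave 41 lower and 8 higher of 84 (47 and 9 adjusted over the list alone, camera adjusted p = 0.000127, and adjusted p = 0.313 with an estimated correlation). The ATP-sensitive channel subunit Kcnj8 rose by 8.13 ± 0.82, and Kcna2 fell by 1.29. Sodium channels fell in 8 of 10, also adjusted over the list alone (camera adjusted p = 0.00186, and adjusted p = 0.277 with an estimated correlation), with Scn2b at -1.41 ± 0.34. Calcium channels fell in 17 of 22 (19 adjusted over the list alone, camera adjusted p = 1.02e-05, and adjusted p = 0.269 with an estimated correlation), with Cacng7 at -1.50 ± 0.21 and Cacnb4 at -1.43 ± 0.43. GABA-A and glycine receptor genes fell in 16 of 22 (18 adjusted over the list alone, camera adjusted p = 7.59e-06, and adjusted p = 0.261 with an estimated correlation), among them Gabra5 (-1.84 ± 0.28). Glutamate receptor genes fell in 18 of 25, also adjusted over the list alone (camera adjusted p = 1.02e-05, and adjusted p = 0.296 with an estimated correlation), with Grik1 at -2.59 ± 0.33 and Gria2 at -1.18 ± 0.36. Nicotinic receptor genes fell in 5 of 11, also adjusted over the list alone (camera adjusted p = 0.017, and adjusted p = 0.261 with an estimated correlation), with Chrnb2 at -1.78 ± 0.29 and Chrna4 at -1.23 ± 0.32. Without IP 2 the lower counts were 23, 4, 9, 12, 7 and 3 in this order, and without IP 1 they were 24, 5, 9, 12, 8 and 4. The nicotinic count was 3 without IP 4 as well. Kcna2, Cacnb4, Gria2 and Scn2b lost their calls without IP 2 (adjusted p = 0.129, 0.0984, 0.111 and 0.0527), and Kcna2, Cacnb4, Gria2 and Chrna4 without IP 1 (adjusted p = 0.133, 0.0862, 0.095 and 0.0558). Kcna2, Cacnb4 and Gria2 lost them without unbound 4 too (adjusted p = 0.0854, 0.0569 and 0.0543), and Kcna2 without unbound 1 or unbound 3 (adjusted p = 0.0638 and 0.0684).

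Long noncoding and nuclear-retained RNAs fell in 12 of 22 and 1 rose, also adjusted over the list alone (camera adjusted p = 0.000255, and adjusted p = 0.184 with an estimated correlation). Malat1, a nuclear RNA, fell from 8059 ± 2903 to 981 ± 849 CPM, Rmst fell by 3.0 on the log2 scale, and Airn rose by 1.94 ± 0.61. That call was lost without IP 1, IP 2, unbound 3 or unbound 4 (adjusted p = 0.0555, 0.19, 0.0592 and 0.0529). Histone genes gave 6 higher and 1 lower of 52, also adjusted over the list alone (camera adjusted p = 0.00754, and adjusted p = 0.54 with an estimated correlation). Hist2h2be rose by 2.0 ± 0.25, Hist3h2ba fell by 2.07, a call lost without IP 2 (adjusted p = 0.0517), and H1f0 had 0.64 ± 0.25 (adjusted p = 0.0613, and 0.00633 without unbound 2). Without unbound 2, 10 histone genes were higher. Nuclear genes of oxidative phosphorylation gave 16 lower and 3 higher of 85 (0 and 2 adjusted over the list alone, camera adjusted p = 0.00677, and adjusted p = 0.677 with an estimated correlation). Cox4i2, a subunit isoform of cytochrome c oxidase, rose by 5.56 ± 0.40, and Atp5b had -0.57 ± 0.26 (adjusted p = 0.102). Without IP 2 the lower count was 0, without IP 1 it was 3 and without IP 4 it was 4, and the list was not called without unbound 2 (adjusted p = 0.146) or IP 4 (adjusted p = 0.0813).

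Cytosolic ribosomal protein genes gave 2 higher of 82 (1 adjusted over the list alone, median 0.07, adjusted p = 0.172), with Rps27l at 1.84 ± 0.38 and Rpl4 at -0.43 ± 0.31 (adjusted p = 0.286). Without unbound 2 the median was 0.70, 44 were higher and the list was called (adjusted p = 4.48e-06). Unbound 2 had 18.7% of its counts in genes in Rn45s, a ribosomal RNA precursor, against 2.17%, 10.5% and 7.34% in unbound 1, 3 and 4. Whether this bears on the results that change without unbound 2 was not tested. Immediate early genes gave 8 higher and 2 lower of 20 (10 and 2 adjusted over the list alone, adjusted p = 0.0821), with Btg2 at 3.13 ± 0.30, Nptx2 at -1.79 ± 0.38 and Egr1 at 0.16 ± 0.53 (adjusted p = 0.835). That list was called as higher without IP 1 (adjusted p = 0.0367) or IP 2 (adjusted p = 0.0239) and with fry (adjusted p = 0.0172). Without IP 4 its median was 0.27 (adjusted p = 0.417) and Egr1 was at -1.09 (adjusted p = 0.0177). Unfolded protein response genes gave 2 higher and 3 lower of 17, also adjusted over the list alone (adjusted p = 0.33), and their median, -0.33, and mean, 0.06, differed in sign. Atf3 rose by 3.11 ± 0.52, and Atf4 had -0.12 ± 0.30. Of 5 sex-linked genes 0 passed in edgeR, over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05 (DESeq2 and limma voom called 0, camera adjusted p = 0.699, direction higher against a median of -0.19), and Ddx3y had 0.58 ± 0.42 (adjusted p = 0.298, and 1.14 with adjusted p = 0.0163 without unbound 4).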

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

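The tests of vascular and of microglial genes and the comparisons of dopaminergic with pan-neuronal genes were chosen after the results were seen. So were the comparison with other splits of the libraries and the leave-out of IP 4 and unbound 2. The expression-matched random lists were written down before their results were seen, but they are not corrected for the choice of the dopaminergic list.

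Of 126 values tested in the 4 unbound libraries, 10 had a library far from the rest by Dixon's ratio at its 95% critical value, and chance gives about 1 in 20. Unbound 1 stood apart at 20.2 CPM for GU332589 (others 9.47 to 10.7), 21.3 for AI450353 (3.34 to 5.94), 1540 for AK018753 (718 to 825) and 74.9 for Gabra5 (52.6 to 55.9). Unbound 2 had 57.2 CPM of Hbb-bs (8.03 to 12.2) and 0.0314% of counts in the erythroid list (0.0189 to 0.0191). Unbound 4 had 0.0882 CPM of BC057675 (others 0), 0.6 of Lcn2 (0.0344 to 0.0877) and 1.73 of Edn3 (2.83 to 3.04). Ripply3 was at 0.038 CPM in unbound 3, under the level of 3 counts there (0.0569 CPM), and 0 in the others. Where all other libraries are at 0, Dixon's ratio is 1 whatever the remaining value. The flags of Ripply3 and BC057675 were therefore fixed in advance and carry no weight. Reads outside genes, which no comparison of genes used, were 16.6% of reads in IP against 12.2% in unbound.

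Endothelial and mural genes were higher in IP although the submitters describe the series as one of neurons. Scaling between libraries does not account for this, since their median log2 fold change was at least 6.4 under 4 scalings, against a shift between scalings of 0.103. A lower share of neurons alone would raise oligodendrocyte genes as well, and these had a median of -1.97 against 6.4 for the 45 vascular genes. The permutation p between these lists was 1e-05, the smallest that 100000 draws can give. Both lists had already been seen to move in opposite directions, so this p carries no weight. The permutation also treats genes as independent, which they are not. A lower share of neurons and oligodendrocytes together was not tested. Tagged ribosomes in vascular cells may account for the pattern, as may vessel RNA held on the beads without the tag, and these cannot be told apart because no immunopurification from an untagged mouse was analysed here. Of the 45 genes, 23 had a higher log2 fold change than Stard8 itself, which decides nothing between them.

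Microglia and macrophage genes were also higher in IP. Perivascular macrophages, attached to vessels, are argued against as the only source, since 8 parenchymal microglia genes of the fixed list, already seen to be higher, had a median of 3.51. Uptake of all macrophage RNA to the same degree is argued against by the difference of medians, 3.07, between 4 perivascular genes of the fixed list (Lyve1, F13a1, Mrc1 and Cd163) and these 8 (exact permutation p = 0.00808, genes not being independent). The list was sorted into the 2 kinds after its values were seen, and its other 11 genes were in neither. Expression of the tag in both kinds of cell, to different degrees, and carry-over of cells with vessels stay open, as no untagged control was analysed here.

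Dopaminergic genes fell less than the other neuronal genes (median -0.37, called as lower by fry with adjusted p = 0.0273 and not by camera, and -0.58 with 8 of 26 lower without both IP 4 and unbound 2). Their mean expression does not account for it, since 0.01% or fewer of 10000 random lists of other neuronal genes matched on expression had a median as high as -0.37 (median of the random lists -1.23). The 2 members that rose do not either, since the other 24 lay 1.26 above the pan-neuronal median (permutation p = 1e-05, the smallest possible). The random lists and this permutation treat genes as independent, which they are not. Neither is corrected for the choice of the dopaminergic list, whose median was the highest of the neuronal lists. The difference from the pan-neuronal median for all 26 was between 0.729 in IP 4 and 1.84 in IP 1, so it does not rest on a single library. The dopaminergic list was not the only neuronal list that camera did not call. Serotonergic and noradrenergic genes had lower medians (-1.1 and -0.79). Neither camera (adjusted p = 0.287 and 0.581) nor fry (adjusted p = 0.476 and 0.738) called those lists. Some tag expression in dopaminergic neurons is a candidate explanation, as a hypothesis, and expression of members outside neurons, stability and ribosome load were not tested.

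Other splits of the libraries into 3 and 4 can be set against the 6950 genes of the real split. Of 35 splits, 1, the real one, gave as many, and the highest of the others gave 1 gene. The exact permutation p for this rank was 0.0286, the smallest that 35 splits can give, so chance is unlikely but not excluded. Every other split mixes IP with unbound libraries, so their low counts follow from the group difference and add no weight. The real split also parts the sequencing lanes, so a lane effect within this count cannot be told apart from the group.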

How the results depend on the processing

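Stard8 kept its direction and its call under every alternative run, with log2 fold changes between 5.67 (within index GTGAAA) and 6.72 (within index ACAGTG), and 6.20 to 6.62 when each library was left out. The number of genes past the threshold was 3840 within index ACAGTG, all with an absolute log2 fold change of at least 1, with 2190 higher and 1650 lower. That setting has fewer libraries. Leaving out each library gave 4547 to 7682 genes in all, 1751 to 3632 lower, 2796 to 4050 higher, and 4349 to 5943 with an absolute log2 fold change of at least 1. The cause of the low counts without IP 1 or IP 2 was not tested beyond the removal of a library. The other alternatives lay within 1.5 times, between 5214 (glmTreat) and 8053 genes (without both IP 4 and unbound 2, chosen after seeing the data). No gene called in the main comparison was called in the opposite direction under any of them. With an estimated correlation 0 lists were called with camera (7 at an unadjusted p under 0.05), against 26 with the preset one, while fry called 27. Over the preset calls, fry added the dopaminergic list as lower (adjusted p = 0.0273) and the ependymal (adjusted p = 0.00348) and immediate early lists (adjusted p = 0.0172) as higher, and it lost histones (adjusted p = 0.105) and oxidative phosphorylation (adjusted p = 0.439). Leaving out each library gave 25 to 28 lists. The cause was not tested. Library size alone moved the median log2 fold change of all genes by 0.103, to 0.01 from -0.10. Egr1 changed from 0.16 to -1.09 without IP 4 (adjusted p = 0.0177), up to 0.56 without another library, and to -1.22 without both IP 4 and unbound 2, and the cause was not tested. Of 84 named genes past the threshold, 68 stayed past it when each library was left out. Differences in the composition measures moved by less than 1 SD (the root of the mean of the 2 group variances) when each library was left out. Small differences could still change sign. The fibroblast share was 0.0642% in IP 1 and 0.0631% in IP 2, below the unbound mean of 0.069%, so its difference changed sign without IP 4.

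The replicate number as a block gave 5772 genes (3154 higher, 2618 lower) and 26 lists. Deviations from the group means correlated at -0.121, 0.0766 and 0.314 for libraries numbered 1, 2 and 4. IP 2 and IP 4 correlated best with the unbound library of their own number, but IP 1 with unbound 2 (0.434). With so few libraries these correlations do not settle whether the numbers mark pairs. With the block Slc6a5 (-2.53, adjusted p = 0.00124), Tph2 (-1.22, adjusted p = 0.0145) and Rpl10a (1.37, adjusted p = 0.0394) passed and Slc6a3 did not (-0.75, adjusted p = 0.0816).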

Other observations

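The 13 lists in this part, and the tests on them, were chosen after the data were examined. Most of the genes listed for the blood-brain barrier and for vessel walls were higher in IP. Of 23 transporters of the barrier 18 rose, among them the efflux pump Abcb1a (6.40) and the organic anion transporter Slco1c1 (5.86), both in the endothelial list, but the list did not pass with an estimated correlation (adjusted p = 0.0578). Outside the fixed lists 13 of 18 rose, median 2.87, among them the lipid transporter Mfsd2a (2.81). Outside those lists, tight and adherens junction genes rose in 7 of 8, median 3.05, arterial genes in 10 of 11, median 4.22, venous genes in 10 of 11, median 4.71, and smooth muscle contraction genes in 6 of 6, median 4.32. Basement membrane genes rose in 11 of 14, median 3.06. Wnt target genes of the endothelium rose in 7 of 10 outside the fixed lists, with Apcdd1 at 5.50 and Axin2 at 1.73, and Plvap, a marker of fenestrated endothelium, fell by 1.68.

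Interferon-stimulated genes rose in 19 of 20, by a median of 3.96, among them Ifitm3 (6.30), Isg15 (5.53) and Ifit1 (4.67), with Irf7 at 2.38 (adjusted p = 0.0879). MHC class I presentation genes rose in 9 of 11, with Psmb8 at 5.93 and B2m at 4.48. Outside the fixed lists, perivascular macrophage genes rose in 8 of 8, median 6.92, parenchymal microglia genes in 4 of 4, median 2.55, and astrocyte endfoot genes in 3 of 4, median 0.81. Sparc was counted among these microglia genes and among the basement membrane genes as well. Dopaminergic core genes gave 1 lower of 13, median -0.20. All 13 were in the fixed dopaminergic list, and the choice left out its 2 higher members and 4 of its 5 lower ones, so this list is no test of that one. With an estimated correlation the MHC class I and endfoot genes did not pass over these 13 lists either (both adjusted p = 0.0692), nor did the dopaminergic core (adjusted p = 0.467). Where others passed this carries no weight, since the lists were chosen with the values known.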
